A study of Mus musculus with 28 samples.

How the data were processed

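The series measured brain RNA from non-transgenic (NTg), PS19 and PS19 Cx3cr1+/- mice of both sexes at about 8.5 months. RNA was taken from brain tissue with a column kit, poly(A) RNA was made into stranded libraries, and these were sequenced as paired ends. The authors deposited 1 table of read counts per gene for 28 libraries, and counts are whole numbers with no normalization. Their notes name cutadapt, FastQC, HISAT2 and StringTie and the genome build mm10, without versions. The counting tool, the annotation and the strand setting are not given in the sources used here. Totals ran from 26 to 33 M counts (M, mega) per library, the table lists 24594 genes by NCBI identifier, and 2196 of them have 0 counts in every library. Identifiers of 24570 genes were matched to a RefSeq gene table, and the 24 unmatched ones held 0.22% of counts. Genes of the mitochondrial genome are absent from the table. Count data of this depth carry counting error only as far as reads are independent molecules, which libraries without molecular identifiers do not show.

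The 28 libraries were fitted together in edgeR 4.0.16 under R 4.3.3 with 1 coefficient for each of 6 groups of genotype and sex. Genes were kept with filterByExpr (minimum count 10, minimum total 15), which left 17268, and libraries were scaled by the trimmed mean of M values. Dispersions were estimated with empirical Bayes shrinkage (common biological coefficient of variation 0.186) and tested by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment within each of 10 comparisons. A gene was called at adjusted p under 0.05. The comparisons were PS19 against NTg, PS19 Cx3cr1+/- against PS19 and PS19 Cx3cr1+/- against NTg in each sex, the first pair of these averaged over the sexes, and the female minus male difference for each of that pair. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists within each comparison. The same test with an estimated correlation was run beside it, as was fry, which asks whether the members move 1 way on balance and does not compare them with other genes. A member was also called "adjusted over the list alone" when its p passed Benjamini-Hochberg adjustment among the members. The model, the comparisons, the lists and the rule for naming genes were chosen before the data were examined.

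There were 37 lists written from general knowledge, of which 36 were tested; the list of mitochondrially encoded respiratory chain genes had 0 members in the table. Immune lists covered homeostatic, disease-associated and border macrophages and microglia, interferon response, antigen presentation, complement, lymphocytes, neutrophils and monocytes, and NF-kB and cytokines. Brain cell lists covered astrocytes, reactive astrocytes, myelinating and precursor oligodendrocytes, excitatory and inhibitory neurons, synapses, immediate early genes, endothelial, mural, meningeal, choroid plexus, ependymal and erythroid cells. Region lists covered striatum, thalamus, hypothalamus and pituitary, cerebellum and hippocampus. Pathway lists covered lysosome and autophagy, unfolded protein and integrated stress response, heat shock, cytosolic ribosomal proteins, nuclear respiratory chain and proteasome. Risk gene lists held genes linked to Alzheimer disease (68 tested) and ALS (63 tested). A list of 20 abundant adult heart transcripts was added after the values were seen.

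Genes were named by rule. The rule took check genes of genotype and sex (Cx3cr1, Mapt, Prnp, Xist, Ddx3y, Eif2s3y, Kdm5d, Uty), then per comparison up to 5 rising and 5 falling called genes with the smallest p and a mean of at least 1 CPM in 1 group, leaving out unnamed predicted genes. It also took up to 3 called members per list, the 3 members of each risk list with the smallest p, every called gene where a comparison called at most 10, and the 2 members with the smallest p of a list that camera called without a called member. Genes named beyond this are marked in the text as chosen after their values were seen.

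Each library's trend on transcript length and GC content was fitted across genes of at least 1 mean CPM with both known from an annotation (93.8% of tested genes). Libraries of NTg and PS19 mice were split at a length slope of 0.1, a split made after the data were seen, and changes between NTg and PS19 were recomputed within each side in a fit that kept the sides apart. PS19 Cx3cr1+/- libraries were not split, so all 5 of a sex were set against the PS19 libraries of 1 side. Alternatives set beforehand were RLE size factors, DESeq2 1.42.0, limma voom with quality weights, no filter, a filter at a mean of 1 CPM, a fit of the compared groups alone, the replicate number as a block, and each library left out in turn. Added after the data were seen were an offset for transcript length and GC content, leaving out 6 or 7 libraries at the ends of the length trend, and leaving out PS19 male replicates 4 and 5. The 6 were the NTg and PS19 libraries with a slope above 0.1, and the 7 held PS19 Cx3cr1+/- male replicate 5 as well. PS19 Cx3cr1+/- females above 0.1 and PS19 male replicate 2 (-0.231) stayed in. Other splits of the same libraries were tested, up to 100 per comparison. The fits were tested on simulated data with 200 changed genes. In PS19 Cx3cr1+/- against PS19 females, 82% of 2-fold and 39% of 1.5-fold changes were called. The share of false calls in edgeR was at most 6.41% over the comparisons simulated. These counts were drawn independently for each gene, without a length trend or a batch, so the rates do not carry over to libraries that differ in such ways. No sample was left out of the main results, and no column was left unmapped.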

Results

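The deposited table holds brain RNA counts from 28 mice aged about 8.5 months in 6 groups of genotype and sex. There were 5 non-transgenic (NTg) females, 5 NTg males, 3 PS19 females, 5 PS19 males, 5 PS19 females with 1 working copy of Cx3cr1 (PS19 Cx3cr1+/-) and 5 such males. PS19 mice carry a human mutant tau transgene under the mouse prion promoter and develop tau pathology with age. Cx3cr1 encodes the receptor through which brain microglia sense the neuronal chemokine fractalkine. Totals per library ran from 26 to 33 M counts (M, mega), with group means of 30.56 M (SD 1.15, n = 5) in NTg females, 30.78 M (SD 0.785, n = 5) in NTg males, 29.47 M (SD 0.379, n = 3) in PS19 females, 29.68 M (SD 1.45, n = 5) in PS19 males, 31.3 M (SD 2.06, n = 5) in PS19 Cx3cr1+/- females and 29.58 M (SD 2.16, n = 5) in PS19 Cx3cr1+/- males. Gene-level values are counts per M (CPM) after scaling, and changes are log2 fold changes with their standard error (SE).

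Genes that report on the genotypes and the sexes came first. Cx3cr1 (NCBI gene 13051, chromosome 9) lay at 15.3 to 37.8 CPM in the 10 PS19 Cx3cr1+/- libraries and at 28.8 to 56.4 CPM in the other 18, so the ranges overlapped. Its mean was 26.6 CPM (SD 2.41, n = 5) in PS19 Cx3cr1+/- females against 36.73 CPM (SD 6.71, n = 3) in PS19 females. Among males it was 26.23 CPM (SD 8.47, n = 5) against 43.04 CPM (SD 11.7, n = 5). Against PS19, Cx3cr1 was lower by a log2 fold change of -0.59 (SE 0.14) over both sexes, which passed edgeR quasi-likelihood at adjusted p = 0.0107, while the females alone (-0.47, SE 0.22, adjusted p = 0.128) and the males alone (-0.71, SE 0.19, adjusted p = 0.0893) did not. The male value depended on the PS19 libraries compared: it was -0.41 (SE 0.18, adjusted p = 0.142) against PS19 male replicates 1 to 3 and -1.07 (SE 0.20, adjusted p = 0.012, edgeR quasi-likelihood) against replicates 4 and 5. These PS19 subsets, set apart by a trend on transcript length described below, differed in Cx3cr1 themselves (0.65, SE 0.22, adjusted p = 0.0364, edgeR quasi-likelihood). The difference between the sexes was 0.25 (adjusted p = 0.692, edgeR quasi-likelihood). Prnp (NCBI gene 19122, chromosome 2), the gene whose promoter drives the transgene, averaged 671.6 CPM (SD 52.7, n = 5) and 639.4 CPM (SD 42.5, n = 5) in NTg females and males. It averaged 1572 CPM (SD 73.3, n = 3) and 1454 CPM (SD 297, n = 5) in PS19 females and males, and every transgenic library lay above every NTg library. PS19 Cx3cr1+/- females averaged 1163 CPM (SD 93.5, n = 5), and all 5 (1055 to 1289 CPM) lay below all 3 PS19 females (1490 to 1631 CPM), a change of -0.44 (SE 0.18) that was not called (adjusted p = 0.093, edgeR quasi-likelihood). PS19 Cx3cr1+/- males averaged 1490 CPM (SD 616, n = 5), with a change of 0.04 (SE 0.16) against PS19. Replicate 5 (2581 CPM, the others 1122 to 1358) carried this mean: without it the change was -0.25, and without 7 libraries at the ends of the length trend, replicate 5 among them, it was -0.42 (adjusted p = 0.0031, edgeR quasi-likelihood). Against PS19 male replicates 1 to 3 and against 4 and 5 it was -0.14 (SE 0.17) and 0.34 (SE 0.20). Within PS19 males, Prnp differed by -0.47 (SE 0.22) between replicates 4 and 5 and replicates 1 to 3 (adjusted p = 0.118, edgeR quasi-likelihood). PS19 and PS19 Cx3cr1+/- females did not overlap on the length trend, so lower Prnp in PS19 Cx3cr1+/- mice cannot be told apart from that trend. Mapt (NCBI gene 17762, chromosome 11), the mouse tau gene, was 615.1 CPM (SD 21.7, n = 5) in NTg females and 674.3 CPM (SD 7.78, n = 3) in PS19 females, and its change of 0.13 (SE 0.07) was not called (adjusted p = 0.432, edgeR quasi-likelihood). Whether transgene reads were counted under Prnp or Mapt is not given in the sources used here. Xist ran from 323.6 CPM upward in females and averaged 9.096 to 17.74 CPM in the male groups. The Y-linked Ddx3y averaged 72.65 to 80.14 CPM in the male groups and 1.924 to 3.347 CPM in the female groups, so every library carried the pattern of its labelled sex.

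**Figure D1:**
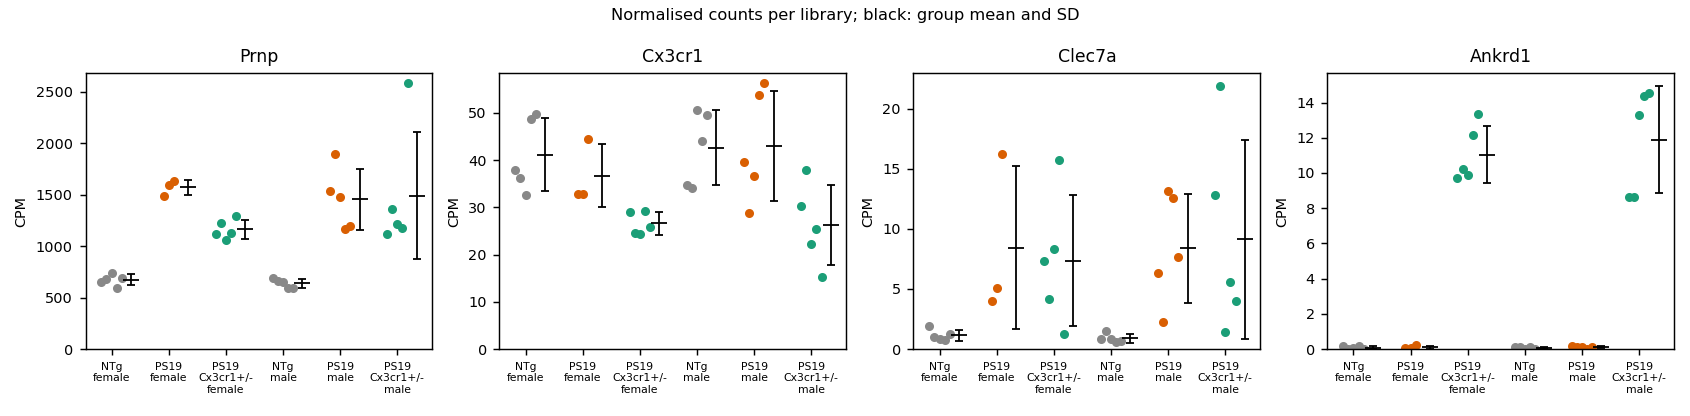
Normalised counts of Prnp, Cx3cr1, Clec7a and Ankrd1 in each of the 28 libraries (CPM on the vertical axis, 1 point per library, black bars for the group mean and SD) by genotype and sex. Prnp is higher in every transgenic library than in every NTg library, Cx3cr1 overlaps between genotypes, and Ankrd1 separates the 10 PS19 Cx3cr1+/- libraries from the other 18.

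Genes called between PS19 and NTg brains by edgeR quasi-likelihood were myeloid transcripts and Prnp. The genes called encode secreted chemokines (Ccl3, Ccl6, Ccl9), immune-cell surface proteins (Slamf8, Clec7a, Cd52) and a cathepsin inhibitor of activated microglia (Cst7). All of them were higher in PS19. With the sexes averaged, 8 genes rose and 0 fell among 17268 tested, with 2347 genes at an unadjusted p under 0.05 where 863 would be expected. Prnp rose by 1.21 (SE 0.12, adjusted p = 1.42e-06), Ccl3 by 2.60 (SE 0.38, adjusted p = 0.00195) and Slamf8 by 1.73 (SE 0.28, adjusted p = 0.00515, edgeR quasi-likelihood). Ccl9 rose by 1.32 (SE 0.22, adjusted p = 0.00515) and Clec7a by 3.06 (SE 0.49, adjusted p = 0.00646, edgeR quasi-likelihood). Ccl6 rose by 1.54 (adjusted p = 0.0199), Cd52 by 1.44 (adjusted p = 0.0314) and Cst7 by 3.68 (SE 0.70, adjusted p = 0.0455, edgeR quasi-likelihood). Clec7a, a glucan receptor that microglia express around damaged tissue, averaged 8.433 CPM (SD 6.78, n = 3) and 8.397 CPM (SD 4.54, n = 5) in PS19 females and males against 1.156 CPM (SD 0.458, n = 5) and 0.879 CPM (SD 0.384, n = 5) in NTg, with all 8 PS19 libraries above all 10 NTg libraries. The count was 5 without NTg female replicate 3, NTg female replicate 4, NTg male replicate 3, NTg male replicate 4 or PS19 male replicate 3, and 4 without PS19 female replicate 3. Prnp, Ccl3, Slamf8 and Ccl9 passed in every refit without 1 library. Clec7a was lost without PS19 female replicate 3 (adjusted p = 0.0555, edgeR quasi-likelihood), and Ccl6 without any of the 6 libraries just named. Cd52 was lost in 10 and Cst7 in 15 of the 18 refits (adjusted p up to 0.117 and 0.159). Number and direction depended on the setting. DESeq2 called 59 genes (39 higher, 20 lower), limma voom 3155 (1472 higher, 1683 lower) and the fit without PS19 male replicates 4 and 5 2070 (838 higher, 1232 lower). Without 6 or 7 libraries at the ends of the length trend, Prnp was the gene called, and the calls of Ccl6, Cd52 and Cst7 also ended with an offset for transcript length and GC content.

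Within the sexes, far fewer genes passed. In females, Prnp alone was called (1.23, SE 0.18, 2.34-fold, adjusted p = 0.00329, edgeR quasi-likelihood), with 2036 genes at an unadjusted p under 0.05. Without NTg female replicate 2 the count was 14, and it was 2 without NTg female replicate 4 or PS19 female replicate 3. DESeq2 called 59 and limma voom 1032. With the replicate number as a block the Prnp call ended. In males, Prnp (1.19, SE 0.16, adjusted p = 0.000829), Ccl3 (2.99, SE 0.54, adjusted p = 0.0375) and Slamf8 (2.20, SE 0.40, adjusted p = 0.0375) were called by edgeR quasi-likelihood, with 555 genes at an unadjusted p under 0.05. The male count was 1 without any of NTg male replicates 1 to 5 and without PS19 male replicate 1, 3 or 4, Ccl3 was also lost without PS19 male replicate 5, and adjusted p for Ccl3 and Slamf8 reached 0.264. Both calls also ended with the replicate block, with the length and GC offset, without 6 or 7 libraries at the ends of the length trend and without PS19 male replicates 4 and 5, and the Ccl3 call with limma voom. Without the 6 libraries the male Prnp call ended as well. Among females with a trend on transcript length at or below 0.1 in each library (3 PS19 and 4 NTg), Prnp was again the gene called, at 1.19 (SE 0.18, adjusted p = 0.00802, edgeR quasi-likelihood). Among males at or below that trend (3 PS19 and 2 NTg), edgeR quasi-likelihood called 0 genes with 318 at an unadjusted p under 0.05. Above it (2 PS19 and 3 NTg) it also called 0, with 304 at that level, and Prnp was higher by 1.28 (SE 0.22) and 0.94 (SE 0.21) in these subsets. Ccl3 was higher by 3.44 (SE 0.87) and 2.54 (SE 0.77) there and Slamf8 by 1.90 (SE 0.55) and 2.32 (SE 0.59), so these changes kept their size while their calls ended with fewer libraries.

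Disease-associated microglial genes were higher as a set in both sexes of PS19 mice, as were antigen presentation and interferon genes, while the homeostatic microglial list was not called. These are calls at the preset correlation, and with an estimated correlation none held (camera adjusted p from 0.097 in males for the disease-associated list to 0.78 in females for interferon genes). Disease-associated microglial genes mark the state of microglia near pathology. Interferon genes mark an antiviral-type response, which whole-brain RNA does not assign to a cell type. The disease-associated list was higher in females with a median of 0.44 over 28 genes (camera adjusted p = 1.51e-05, adjusted p = 0.641 with an estimated correlation), with 0 members called over all genes and 12 higher and 1 lower adjusted over the list alone. In males the median was 0.61 (camera adjusted p = 1.77e-25, adjusted p = 0.097 with an estimated correlation), with 1 member called over all genes and 15 higher adjusted over the list alone. Its medians were 0.42 in the females with the trend at or below 0.1, and 0.42 and 0.74 in the male subsets. Interferon response genes (Mx1, Rtp4, Bst2) had medians of 0.26 in females (camera adjusted p = 0.0365, adjusted p = 0.78 with an estimated correlation) and 0.41 in males (camera adjusted p = 1.28e-09, adjusted p = 0.296 with an estimated correlation). The female interferon call was lost without NTg female replicate 2, NTg female replicate 3 or PS19 female replicate 3. It was also lost with the length and GC offset (camera adjusted p = 0.0671) and without 6 (0.0582) or 7 (0.111) libraries at the ends of the length trend. Antigen presentation genes (Cd74, H2-Q6, H2-D1, Psmb8) had medians of 0.39 in females (camera adjusted p = 0.000445, adjusted p = 0.641 with an estimated correlation), a call lost without PS19 female replicate 3, and 0.38 in males (camera adjusted p = 5.07e-09, adjusted p = 0.176 with an estimated correlation). No list in any comparison held with an estimated correlation. Tested by fry, which does not compare a list with other genes, lists were called in 3 of the 10 comparisons. For PS19 against NTg over both sexes these were disease-associated microglial (higher) and hippocampal genes (lower), each at fry adjusted p = 0.0394. For PS19 Cx3cr1+/- against PS19 over both sexes they were endothelial (higher, 0.0353), thalamic (higher, 0.0369), immediate early (lower, 0.0369) and ribosomal genes (lower, 0.0461). For PS19 Cx3cr1+/- against NTg males they were disease-associated microglial (higher), reactive astrocyte (higher) and immediate early genes (lower), each at fry adjusted p = 0.0451.

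Other lists were called in 1 or both sexes of PS19 mice. In males, complement genes (C1qc, C4b) had a median of 0.43 (camera adjusted p = 2.26e-07, adjusted p = 0.176 with an estimated correlation), with 9 of 16 higher adjusted over the list alone. Reactive astrocyte genes (C4b, Tgm1) had a median of 0.25 in males (camera adjusted p = 2.34e-06, adjusted p = 0.176 with an estimated correlation), with 6 of 24 higher adjusted over the list alone. Lysosomal genes (Ctsd, Ctss) were also higher in males (median 0.11, camera adjusted p = 1.16e-05, adjusted p = 0.286 with an estimated correlation). Synapse genes (Dlg4, Cplx2) were lower in males (median -0.15, camera adjusted p = 4.7e-06), as were hippocampal genes (Dsp, Lct; median -0.16, camera adjusted p = 5.54e-05), with adjusted p = 0.176 and 0.117 with an estimated correlation. Excitatory neuron genes (Camk2a, Wfs1) were lower in males too (median -0.15, camera adjusted p = 0.000453, adjusted p = 0.176 with an estimated correlation), a call lost without PS19 male replicate 3. In females, thalamic genes (Shox2, Rgs16) were lower with a median of -0.70 (camera adjusted p = 5.18e-06, adjusted p = 0.641 with an estimated correlation) and 9 of 14 lower adjusted over the list alone. Myelinating oligodendrocyte genes (Ugt8a, Fa2h; median -0.22, camera adjusted p = 0.000274) and oligodendrocyte precursor genes (Lhfpl3, Pdgfra; median -0.27, camera adjusted p = 0.000624) were lower in females, each at adjusted p = 0.641 with an estimated correlation. In males the myelinating list was called higher (median 0.07, camera adjusted p = 0.0264, adjusted p = 0.628 with an estimated correlation), a call lost in 7 of 10 refits without 1 library. Cytosolic ribosomal protein genes (Rps18, Rpl35a) had a female median of 0.37 (camera adjusted p = 3.09e-13, adjusted p = 0.641 with an estimated correlation) and 0 of 82 members called over all genes or adjusted over the list alone. Their male median was 0.18 (camera adjusted p = 1.29e-07, adjusted p = 0.628 with an estimated correlation), a call lost without PS19 male replicate 2 and with the length and GC offset (adjusted p = 0.287). The median was 0.15 and -0.07 in the male subsets.

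**Figure D2:**
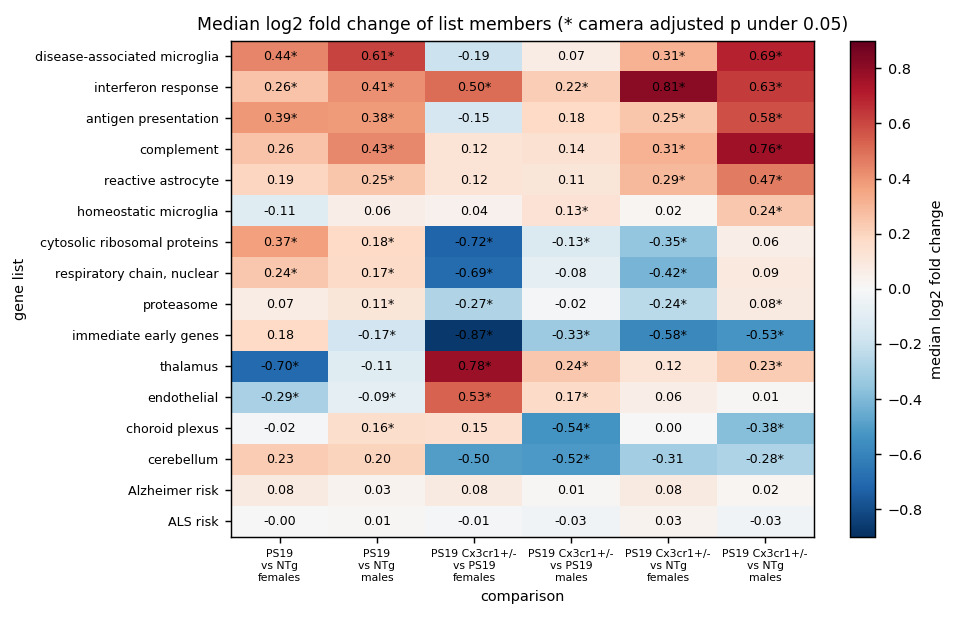
Median log2 fold change of the members of 16 gene lists (rows) in 6 comparisons (columns), with colour and printed value giving the median and an asterisk marking a camera adjusted p under 0.05 at the preset correlation. Disease-associated microglial genes are higher in PS19 than in NTg of both sexes (0.44 and 0.61), and ribosomal and respiratory chain genes are lower in PS19 Cx3cr1+/- than in PS19 females (-0.72 and -0.69).

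Libraries differed within genotypes in how their counts followed transcript length. The trend is the slope of log2 counts on log2 transcript length, in log2 units per SD of length, measured against the mean of all libraries. It averaged -0.1257 (SD 0.0175, n = 3) in PS19 females and 0.0752 (SD 0.0623, n = 5) in PS19 Cx3cr1+/- females, and all 5 of the latter lay above all 3 of the former. It split NTg males (0.136, 0.163 and 0.167 in replicates 3, 4 and 5, -0.123 and -0.039 in replicates 1 and 2), and it lay above 0.1 in NTg female replicate 4, PS19 male replicates 4 and 5 and PS19 Cx3cr1+/- female replicates 1 (0.111) and 3 (0.138) as well. NTg males have 1 genotype, yet replicates 3 to 5 differed from replicates 1 and 2 in 2579 genes by edgeR quasi-likelihood, a count inflated by sorting the libraries on their own values. Between them, the medians were -0.51 for ribosomal, -0.43 for respiratory chain, -0.35 for immediate early, 0.71 for thalamic and 0.40 for endothelial genes. Across genes, which are not independent replicates, this difference correlated at -0.44 with the change of PS19 against NTg in females. The thalamic fall and the ribosomal rise in PS19 females thus ran along the trend. Their medians were -0.69 and 0.31 among females at or below 0.1, but that subset does not remove the trend. All 3 PS19 females (-0.145 to -0.111) lay below the 4 NTg females kept in it (-0.099 to -0.016). Both calls held with the length and GC offset. The ribosomal RNA precursor Rn45s averaged 3316 CPM (SD 666, n = 3) in PS19 females and 1081 CPM (SD 133, n = 5) in PS19 Cx3cr1+/- females.

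**Figure D3:**
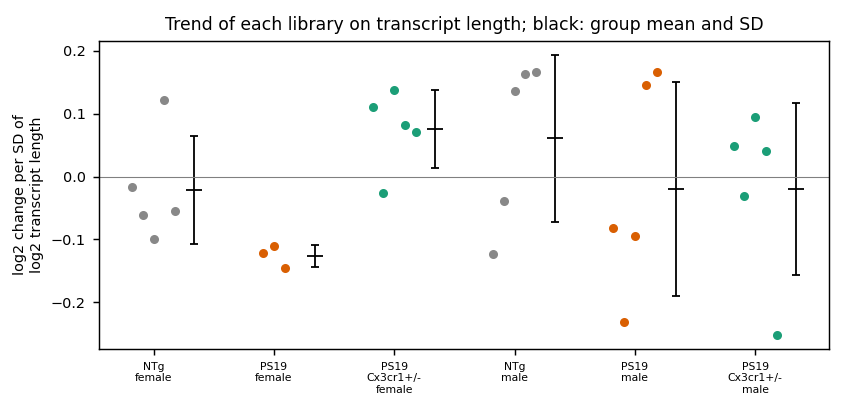
Slope of each library on transcript length (log2 change per SD of log2 length, vertical axis) by group, with 1 point per library and black bars for the group mean and SD. All 3 PS19 females lie below all 5 PS19 Cx3cr1+/- females, and NTg and PS19 males each split into a lower and a higher set.

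In every comparison with PS19 Cx3cr1+/- mice, a library batch shared by those animals cannot be told apart from the genotype. Against PS19 females, PS19 Cx3cr1+/- females had lower transcripts for protein synthesis and respiration at the preset correlation of the list test. Thalamic, endothelial and interferon transcripts were higher at that correlation. With an estimated correlation none of these lists was called (camera adjusted p = 0.916 for each). Genes that neurons switch on within minutes of activity (Egr4, Junb, Ier2) were lower. Some heart-muscle genes were higher in these brains, as they were in males. Sall1, which encodes a factor that keeps microglial identity, rose. The lipid carrier gene Apoe fell, a call that ended with the length and GC offset, and whole-brain RNA does not show in which cells it fell. edgeR quasi-likelihood called 2552 genes, 1037 higher and 1515 lower, with 5929 at an unadjusted p under 0.05. This count moved with the libraries. Without PS19 female replicate 2 it was 111, without PS19 female replicate 1 it was 138 and without PS19 female replicate 3 it was 999. Without PS19 Cx3cr1+/- female replicate 3, 1 or 4 it was 797, 914 or 1683. DESeq2 called 3481 and limma voom 8558. No PS19 female library had a length trend above 0.1, so no value within the higher subset can be given. With the groups of NTg and PS19 split on that trend and PS19 Cx3cr1+/- left whole, the same females gave 5043 calls, a value that still holds the difference in trend between the 2 groups. Of the 2552 genes, 850 also differed in the same direction between NTg male replicates 3 to 5 and 1 to 2, and 4 differed in the opposite direction. If genes were independent, 181 and 200 would be expected.

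Named genes of this comparison came from several cell types. Of 86 named genes called, 18 passed in every refit without 1 library, 64 were lost without PS19 female replicate 1 and 66 without PS19 female replicate 2. Without PS19 Cx3cr1+/- female replicates 3, 1, 4, 2 and 5, 41, 38, 18, 7 and 5 were lost, and without PS19 female replicate 3, 36 were lost. Genes that passed in each refit included Phyhip, a neuronal interactor of a peroxisomal enzyme (-0.58, SE 0.10, adjusted p = 0.0025), and Tceal5, a transcription elongation factor relative (-0.76, SE 0.13, adjusted p = 0.00275, edgeR quasi-likelihood). Neurod2, a transcription factor of cortical excitatory neurons, fell by 0.72 (SE 0.13, adjusted p = 0.00275) and Col9a3, a collagen chain, fell by 0.94 (SE 0.17, adjusted p = 0.00279, edgeR quasi-likelihood). Hypk, a chaperone of newly made proteins, fell by 1.01 (SE 0.19, adjusted p = 0.00426, edgeR quasi-likelihood). Slc17a6, the glutamate transporter of subcortical neurons, rose by 1.26 (SE 0.22, adjusted p = 0.00275), and Lhfpl3 of oligodendrocyte precursors rose by 0.78 (SE 0.14, adjusted p = 0.0026, edgeR quasi-likelihood). The stress-response factor Ddit3 fell by 0.59 (SE 0.12, adjusted p = 0.00924, edgeR quasi-likelihood). Sall1 rose by 1.22 (SE 0.23, adjusted p = 0.00425, edgeR quasi-likelihood), and this call was lost without PS19 female replicate 2 (adjusted p = 0.0503). Apoe fell by 0.62 (SE 0.18, adjusted p = 0.0258, edgeR quasi-likelihood), and this call was lost without PS19 female replicate 1, 2 or 3 or PS19 Cx3cr1+/- female replicate 1 or 3 (adjusted p up to 0.137). With the length and GC offset the calls of Apoe, Ddit3 and Igf1 ended, as did those of Junb, Ier2, Parp14, Rsad2, Abcb1a, Entpd1 and Ltc4s. Of the disease-associated microglial list, Igf1 (0.65, adjusted p = 0.0226) and Timp2 (0.61, adjusted p = 0.00924, edgeR quasi-likelihood) rose, and the list itself was not called (median -0.19). Inhibitory neuron genes went both ways, with Gad2 higher (0.97, adjusted p = 0.00892) and Pvalb and Cort lower (-1.34 and -1.71, each at adjusted p = 0.0104, edgeR quasi-likelihood).

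As sets, 7 of 36 lists were called in PS19 Cx3cr1+/- females, each at adjusted p = 0.916 with an estimated correlation. Of 82 cytosolic ribosomal protein genes, which build the translation machinery, 52 fell and 0 rose, with 71 lower and 1 higher adjusted over the list alone (median -0.72, camera adjusted p = 3.58e-22). Rps15 (-1.18), Rpl31 (-0.97) and Rpl21 (-0.98) were the members with the smallest p. Of 81 nuclear respiratory chain genes, 48 fell and 2 rose, with 60 lower and 3 higher adjusted over the list alone (median -0.69, camera adjusted p = 9.12e-17). Cox6a2 (-1.31), Ndufa13 (-1.23) and Uqcr10 (-1.07) led the falls, and Ndufs1 (0.32) and Sdha (0.31), chosen after their values were seen, were the members that rose. Proteasome genes had a median of -0.27 (camera adjusted p = 0.000369), with 7 lower (Psmb10, Psmd4) and 1 higher (Psmd1), and 13 lower and 1 higher adjusted over the list alone, and the call ended with the length and GC offset (adjusted p = 0.22). Immediate early genes (Egr4 -1.19, Junb -1.19, Ier2) had a median of -0.87 (camera adjusted p = 0.00262), with 7 of 18 lower and 9 adjusted over the list alone. Thalamic genes (Shox2 1.14, Slitrk6 1.71, Tcf7l2 1.05) had a median of 0.78 (camera adjusted p = 0.000369), with 8 of 14 higher and 9 adjusted over the list alone. Endothelial genes had a median of 0.53 (camera adjusted p = 0.0013), with 5 of 15 higher (Kdr, Cdh5, Abcb1a and, chosen after their values were seen, Pecam1 and Tek) and 7 adjusted over the list alone. Interferon genes had a median of 0.50 (camera adjusted p = 0.000838), with 4 of 26 higher (Ifit2, Parp14, Rsad2 and, chosen after its value was seen, Ifit1) and 4 adjusted over the list alone. Homeostatic microglial genes had a median of 0.04, with Sall1 and Entpd1 higher and Ltc4s lower. Called lists other than interferon (0.07) moved the same way between NTg male replicates 3 to 5 and 1 and 2. Those medians were -0.51 for ribosomal, -0.43 for respiratory chain, -0.30 for proteasome and -0.35 for immediate early genes. They were 0.71 for thalamic and 0.40 for endothelial genes, so these female changes cannot be told apart from the length trend.

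Against PS19 males, PS19 Cx3cr1+/- males showed the same rise of some heart-muscle genes and, with all libraries, few other calls. Sall1 and Dlx1, a factor of inhibitory neurons, rose, and Col9a3 fell as it did in females. Genes of the choroid plexus, which makes cerebrospinal fluid, and of the cerebellum were lower as sets at the preset correlation, each at adjusted p = 0.458 with an estimated correlation, and their levels were uneven among the PS19 Cx3cr1+/- males. edgeR quasi-likelihood called 89 genes, 74 higher and 15 lower, with 1586 at an unadjusted p under 0.05. The count was 35 without PS19 male replicate 3, 36 without PS19 Cx3cr1+/- male replicate 3 and 161 without PS19 Cx3cr1+/- male replicate 5. It was 1689 against the 3 PS19 males with a length trend at or below 0.1 and 45 against the 2 above it, in a fit with these subsets apart. DESeq2 called 212 and limma voom 48. Without 6 or 7 libraries at the ends of the length trend, edgeR quasi-likelihood called 1097 and 3707. Col9a3 fell by 0.89 (SE 0.15, adjusted p = 0.00238, edgeR quasi-likelihood) and kept its call in each refit without 1 library. Flt3, a cytokine receptor, fell by 0.45 (SE 0.09, adjusted p = 0.0155), and this call was lost without replicate 3 of either male group (adjusted p up to 0.0709, edgeR quasi-likelihood). Plk5 (-0.68, adjusted p = 0.0284), Grin2c (-0.72, adjusted p = 0.0286), Stap2 (-0.90, adjusted p = 0.0286), Sall1 (0.88, SE 0.19, adjusted p = 0.0256) and Dlx1 (1.05, SE 0.25, adjusted p = 0.0499) passed edgeR quasi-likelihood with all libraries. Of 13 named genes called, 7 were lost without replicate 3 of either group, and 6 passed in every refit. Leaving out PS19 male replicates 1, 2, 4 and 5 lost 6, 4, 2 and 3 of them, and leaving out PS19 Cx3cr1+/- male replicates 1, 2, 4 and 5 lost 3, 4, 3 and 1.

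Of 36 lists in males, 14 were called at the preset correlation. Choroid plexus genes (Cldn2, Kcnj13) had a median of -0.54 and cerebellar genes (Barhl2, Fat2) a median of -0.52, each at camera adjusted p = 4.16e-09 and adjusted p = 0.458 with an estimated correlation, with 0 members called over all genes or adjusted over the list alone. Libraries differed widely in these genes: PS19 Cx3cr1+/- male replicates 2 and 3 had 4.756 and 5.405 CPM of Gabra6, 0.4725 and 1.115 CPM of Pcp2 and 67.41 and 160 CPM of Ttr, and replicate 5 had 183, 35.35 and 1465 CPM. Immediate early genes (Nr4a3, Egr2) were lower (median -0.33, camera adjusted p = 0.000296, adjusted p = 0.458 with an estimated correlation), with 1 lower adjusted over the list alone. Endothelial genes (Ly6c1, Itm2a) were higher (median 0.17, camera adjusted p = 0.000205), and neutrophil and monocyte genes (Ly6c2, Retnlg) were higher (median 1.25, camera adjusted p = 3.04e-05), both at adjusted p = 0.458 with an estimated correlation. Homeostatic microglial genes had a median of 0.13 (camera adjusted p = 0.00662, adjusted p = 0.469 with an estimated correlation), a call lost without PS19 Cx3cr1+/- male replicate 2. Ribosomal genes (Rps27, Rpl7l1) had a median of -0.13 (camera adjusted p = 0.0238, adjusted p = 0.833 with an estimated correlation), a call lost without replicate 1, 2 or 3 of either group. Their median was -0.37 against the PS19 males with the lower length trend and 0.35 against those with the higher, so its direction differed between the subsets. For respiratory chain genes these medians were -0.30 and 0.35, and for endothelial genes 0.44 and -0.17. Immediate early genes were lower against both subsets (-0.53 and -0.17).

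Averaged over the sexes, 2419 genes differed between PS19 Cx3cr1+/- and PS19 by edgeR quasi-likelihood, 1067 higher and 1352 lower, with 5602 at an unadjusted p under 0.05. The microglial identity gene Sall1, the inhibitory neuron gene Gad1 and the collagen gene Col3a1 rose, while their lists (homeostatic microglia, inhibitory neuron, meningeal fibroblast) were not called. Ribosomal and immediate early genes were lower as sets at the preset correlation, each at adjusted p = 0.818 with an estimated correlation. Sall1 rose by 1.05 (SE 0.15, adjusted p = 8.12e-05), Gad1 by 0.44 (SE 0.08, adjusted p = 0.00119) and Col3a1 by 2.19 (SE 0.40, adjusted p = 0.00159, edgeR quasi-likelihood). Stap2 (adjusted p = 0.000146), Plk5 (-0.76, SE 0.11, adjusted p = 0.000131) and Tmem145 (-0.61, SE 0.09, adjusted p = 0.000205) fell (edgeR quasi-likelihood). Cytosolic ribosomal genes had 38 of 82 lower (median -0.42, camera adjusted p = 5.6e-17, adjusted p = 0.818 with an estimated correlation). The count was 1061 without PS19 female replicate 1, 1117 without PS19 female replicate 2, 1454 without PS19 Cx3cr1+/- female replicate 3, 1459 without PS19 male replicate 3 and 1470 without PS19 Cx3cr1+/- female replicate 1. It was 1490 without PS19 male replicate 1, 1537 without PS19 male replicate 2, 3664 without PS19 male replicate 5, 3704 without PS19 male replicate 4 and 4198 without PS19 Cx3cr1+/- male replicate 5. Of 86 named genes called, 53 passed in every refit, and the largest losses were 30 without PS19 female replicate 2 and 27 without PS19 female replicate 1.

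Risk genes of Alzheimer disease and amyotrophic lateral sclerosis (ALS), which the series title puts at its centre, changed singly and in both directions. Apoe, Bin1 and Sod1 were lower in PS19 Cx3cr1+/- than in PS19 females, and the polyglutamine gene Atxn2 was higher. Neither list was called as a set in any of the 10 comparisons. In females, 5 of 68 Alzheimer genes rose and 2 fell, the same counts as adjusted over the list alone (median 0.08, camera adjusted p = 0.545). Hs3st5, a heparan sulphate enzyme, rose by 0.67 (SE 0.16, adjusted p = 0.0119), Jazf1 by 0.37 (SE 0.10, adjusted p = 0.0202) and Fermt2 by 0.44 (SE 0.12, adjusted p = 0.0209, edgeR quasi-likelihood). Apoe, named above, fell, and the other members called, chosen after their values were seen, were Cr1l (0.49) and Prkd3 (0.48), which rose, and Bin1 (-0.50), which fell. Of 63 ALS genes, 2 rose and 4 fell, again as adjusted over the list alone (median -0.01, mean 0.03, camera direction up at adjusted p = 0.886, so the signs differed). Over all 17268 tested genes, 14.8% were called in this comparison, a larger share than in either risk list. The calls thus do not set risk genes apart from other genes. Kank1 rose by 0.62 (SE 0.15, adjusted p = 0.0126), Atxn2 rose by 0.61 (SE 0.16, adjusted p = 0.0165) and the RNA-binding Taf15 fell by 0.45 (SE 0.12, adjusted p = 0.0217, edgeR quasi-likelihood). Sod1 (-0.58), Dnajc7 (-0.32) and Dao (-0.83), chosen after their values were seen, also fell. Calls of Hs3st5, Kank1, Atxn2, Jazf1, Fermt2 and Taf15 were each lost without PS19 female replicate 1 or 2, with adjusted p up to 0.0773, 0.0693, 0.0785, 0.109, 0.0822 and 0.0932 (edgeR quasi-likelihood). Jazf1, Fermt2 and Taf15 were also lost without PS19 Cx3cr1+/- female replicate 3, Fermt2 without PS19 Cx3cr1+/- female replicate 1, and Fermt2 and Taf15 without PS19 female replicate 3. The Taf15 call also ended with the length and GC offset.

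In males, Dao, which breaks down D-serine, was the ALS gene called (-0.97, SE 0.23, adjusted p = 0.0457, edgeR quasi-likelihood). This call was lost without PS19 male replicate 1, 2, 3 or 4 or PS19 Cx3cr1+/- male replicate 2, 3 or 4 (adjusted p up to 0.221), and with the stricter filter, the replicate block or the length and GC offset. Among Alzheimer genes, edgeR quasi-likelihood called 0 of 68 in males over all genes and 1 lower adjusted over the list alone, and Abca7 came closest (-0.56, SE 0.14, adjusted p = 0.0503). The female and male changes were compared directly, and no risk gene passed. The smallest p belonged to Klf16 (-0.59), Cr1l (0.50) and Chchd10 (-0.81), each at adjusted p = 0.354 (edgeR quasi-likelihood). For Prkd3 (0.50) it was adjusted p = 0.356, for Vapb (0.27) 0.36 and for Sod1 (-0.52) 0.362 (edgeR quasi-likelihood). In PS19 against NTg, 0 risk genes were called in either sex by edgeR quasi-likelihood. Trem2, the microglial lipid receptor, was higher by 0.90 (SE 0.29, adjusted p = 0.296) in females and 0.82 (SE 0.26, adjusted p = 0.98, edgeR quasi-likelihood) in males, short of the threshold.

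Ankrd1, Myh6, Myh7, Actc1 and Myl7, which are heart-muscle genes, separated PS19 Cx3cr1+/- brains from all others in both sexes, while of 18 abundant adult heart transcripts 6 were called higher, 2 (Cox6a2, Fabp3) lower and 10 neither (median 0.23). Ankrd1 encodes a stress-induced nuclear protein of heart muscle, Myh6 and Myh7 the heavy chains of cardiac myosin, Actc1 cardiac actin and Myl7 an atrial myosin light chain. Ankrd1 (NCBI gene 107765, chromosome 19) ran from 8.63 to 14.6 CPM in the 10 PS19 Cx3cr1+/- libraries and from 0 to 0.202 CPM in the other 18. Against PS19 it rose by 6.73 (SE 0.55, adjusted p = 6.49e-09) in females and 6.74 (SE 0.43, adjusted p = 3.29e-11) in males (edgeR quasi-likelihood). Myh6 rose by 2.15 (adjusted p = 6.49e-09) and 2.13 (adjusted p = 6.84e-11) and Myh7 by 2.15 (adjusted p = 3.82e-06) and 2.23 (adjusted p = 2.38e-08, edgeR quasi-likelihood). Actc1 rose by 4.40 and 4.55, and Myl7 rose by 4.95 and 4.57. Each of these genes kept its call in every refit without 1 library, and Ankrd1 and Myh6 also rose against the PS19 males of either length-trend subset (6.39 and 7.65 for Ankrd1, 2.10 and 2.19 for Myh6). Myh6 and Myh7 are close paralogs, and how reads that match both were counted is not given in the sources used here. Over all genes, 20 lay higher in all 10 PS19 Cx3cr1+/- libraries than in any of the other 18, and 1 lay lower. In 100 random sets of 10 libraries the highest number above was 0. Beyond those named, the 20 included, chosen after their values were seen, H19, Acta1, Ttn, Csrp3, Myoz2, Hand2, Krt5, Krt13, Krt6a and Krt6b.

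Against NTg, PS19 Cx3cr1+/- mice showed higher Prnp, the heart-muscle genes named above and inflammatory genes. In females, interferon genes (Ifit1, Ifit2) and the growth factor Igf1 rose. In males, the chemokines Ccl3 and Ccl6, the receptor Clec7a and the antigen-presenting B2m rose. edgeR quasi-likelihood called 76 genes in females, 73 higher and 3 lower, and 68 in males, 66 higher and 2 lower, with 2453 and 1527 at an unadjusted p under 0.05. The balance of directions in females depended on the setting, with 170 higher and 278 lower in a fit of the compared groups alone, 1173 and 2168 with limma voom, 472 and 760 without 6 libraries at the ends of the length trend, 1326 and 1615 without 7, and 163 and 34 with DESeq2. In males limma voom gave 124 and 48 and the fit without 7 libraries 136 and 134. Prnp rose by 0.79 (SE 0.16, adjusted p = 0.0171) in females and 1.22 (SE 0.16, adjusted p = 4.01e-05) in males (edgeR quasi-likelihood), and the female call was lost without NTg female replicate 2 or 5 (adjusted p up to 0.0696). Ankrd1 rose by 7.17 and 7.27 and Myh6 by 2.30 in each sex. Female rises were Ifit2 (0.55, adjusted p = 0.0223), Igf1 (0.74, adjusted p = 0.0238), Ifit1 (1.21, adjusted p = 0.0365), Sall1 (0.85, adjusted p = 0.0382), Col1a1 (1.18, adjusted p = 0.0122) and Col3a1 (2.41, adjusted p = 0.0266, edgeR quasi-likelihood). Alpl (-0.53), Phyhip (-0.39) and Syndig1 (-0.47) fell. Male rises were Ccl3 (2.84, adjusted p = 0.011), Clec7a (3.37, adjusted p = 0.0228), Ccl6 (1.79, adjusted p = 0.0237), C1s1 (0.79, adjusted p = 0.0387), Hpgd (0.69, adjusted p = 0.041), B2m (0.81, adjusted p = 0.0454) and Cbr2 (1.67, adjusted p = 0.0492, edgeR quasi-likelihood). St8sia5 (-0.43) and Doc2b (-0.45) fell. Calls other than the heart-muscle genes and the male Prnp call were each lost without at least 1 library, with 10 of 15 female and 10 of 16 male named genes affected. The male calls of Ccl3, Clec7a, Ccl6, C1s1, Hpgd, B2m and Cbr2 also ended with limma voom and without 6 or 7 libraries at the ends of the length trend.

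The counts against NTg moved with the libraries. In females it was 22 without NTg replicate 5, 28 without NTg replicate 2, 30 without NTg replicate 3 and 47 without NTg replicate 4. Leaving out PS19 Cx3cr1+/- female replicates 3, 1, 2 and 4 gave 27, 31, 38 and 120. In males it was 21, 22, 28 and 32 without NTg replicates 5, 4, 3 and 2, 31 without PS19 Cx3cr1+/- male replicate 1 and 114 without PS19 Cx3cr1+/- male replicate 5. Interferon genes formed the list with the largest female median among those of immune function (0.81, camera adjusted p = 2.1e-16, adjusted p = 0.554 with an estimated correlation), with 2 of 26 higher and 21 adjusted over the list alone. Disease-associated microglial genes had medians of 0.31 in females (camera adjusted p = 8.06e-06, adjusted p = 0.566 with an estimated correlation) and 0.69 in males (camera adjusted p = 1.97e-18, adjusted p = 0.127 with an estimated correlation), with 9 and 19 of 28 higher adjusted over the list alone. Reactive astrocyte genes (Serpina3n, Osmr) had medians of 0.29 (camera adjusted p = 9.98e-06, adjusted p = 0.554 with an estimated correlation) and 0.47 (camera adjusted p = 5.91e-09, adjusted p = 0.127 with an estimated correlation). Immediate early genes had medians of -0.58 (camera adjusted p = 0.000114, adjusted p = 0.554 with an estimated correlation) and -0.53 (camera adjusted p = 1.55e-10, adjusted p = 0.127 with an estimated correlation), and 9 of 18 were lower in males adjusted over the list alone. Respiratory chain genes were lower in females (median -0.42, camera adjusted p = 2.89e-20, adjusted p = 0.554 with an estimated correlation).

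Differences between the sexes were tested directly, since a call in 1 sex and not in the other does not show one. For PS19 against NTg, edgeR quasi-likelihood called 0 genes with 613 at an unadjusted p under 0.05, and DESeq2 and limma voom each called 0. For PS19 Cx3cr1+/- against PS19, edgeR quasi-likelihood called 0 with 2276 at an unadjusted p under 0.05, where 863 would be expected, DESeq2 called 6 and limma voom 1. The number at that level was 892 without 6 libraries at the ends of the length trend, 1192 without 7, 724 without PS19 male replicates 4 and 5 and 1959 with the length and GC offset. Without PS19 male replicate 1 or 2 the count was 1, and without PS19 female replicate 3 it was 2. Simulated genes with a difference of 2-fold between the sexes, in data without a length trend, were called in 54% of cases. Across genes, which are not independent replicates, female and male changes correlated at Pearson 0.50 and Spearman 0.39 for PS19 Cx3cr1+/- against PS19. For PS19 against NTg the values were 0.29 and 0.41, and the Pearson value was 0.17 without PS19 male replicate 2, 0.18 without PS19 female replicate 3, 0.12 without 6 or 7 libraries at the ends of the length trend and 0.46 with the stricter filter. Of the genes called in females and in males, 64 were shared in direction, where 5.76 would be expected if genes were independent. In males, 85% of the female calls had the same sign, against 64.1% of all genes. Among the female calls the median absolute change was 0.64, against a male median of 0.14 in the female direction.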

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

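Tests of heart RNA, of a shared batch, of PS19 male replicates 4 and 5, of the 7 libraries at the ends of the length trend and of a smooth trend as the whole cause were chosen after the result was seen. Of 104 groups of libraries over 21 measures, 6 held a library far from the rest by Dixon's test, where chance flags about 1 in 20 groups, or 5.2 here. PS19 Cx3cr1+/- male replicate 5 had 2581 CPM of Prnp (the others 1122 to 1358) and 115.4 CPM of Ddx3y (the others 60.95 to 75.24). NTg male replicate 2 had 0.6824 CPM of Actc1, PS19 Cx3cr1+/- female replicate 2 had 55.35 CPM of Gabra6, PS19 male replicate 1 had 2.887 CPM of Omp and NTg female replicate 5 had 0.1018 CPM of Scgb1a1.

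Gene lists differed between the sexes by camera at the preset correlation, and none did with an estimated correlation, where the smallest adjusted p was 0.481 for PS19 against NTg and 0.917 for PS19 Cx3cr1+/- against PS19. For PS19 against NTg, female minus male medians were -0.30 for myelinating oligodendrocyte genes (camera adjusted p = 1.46e-07), -0.65 for thalamic (2.54e-05), 0.18 for ribosomal (0.000147), 0.38 for immediate early (0.00178), -0.17 for astrocyte (0.00402) and -0.15 for oligodendrocyte precursor genes (0.00423). They were -0.10 for lysosomal (0.01), 0.49 for ependymal (0.0116), -0.15 for heat shock (0.0295), 0.11 for synapse (0.0396), -0.15 for disease-associated microglial (0.0398), -1.28 for erythroid (0.0398), 0.20 for excitatory neuron (0.0434) and -0.14 for homeostatic microglial genes (0.0434). For PS19 Cx3cr1+/- against PS19 they were -0.58 for ribosomal (2.47e-20), -0.60 for respiratory chain (4.16e-16), 0.60 for choroid plexus (9.14e-05), -0.27 for proteasome (0.000445), 0.30 for interferon (0.0437) and 0.52 for thalamic genes (0.0474). Astrocyte, myelinating oligodendrocyte, oligodendrocyte precursor, immediate early and thalamic genes in the first comparison, and choroid plexus, ribosomal, respiratory chain and proteasome genes in the other, passed in each of the 18 refits without 1 library. The ribosomal call in the first comparison was lost without PS19 male replicate 5, the ependymal call without NTg female replicate 4, and the lysosomal call without PS19 male replicate 1 or PS19 female replicate 2; heat shock was lost in 6 refits, erythroid in 8, homeostatic in 9, and disease-associated, excitatory neuron and synapse genes in 10 each. Interferon and thalamic genes in the other comparison were lost in 9 and 12 refits, and the proteasome call ended with the length and GC offset (adjusted p = 0.767). Without 6 or 7 libraries at the ends of the length trend, 6 and 7 of the 14 lists of the first comparison kept their call. In the other comparison, 4 and 4 of its 6 lists did.

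Ankrd1, Myh6, Myh7, Actc1 and Myl7 were higher in all 10 PS19 Cx3cr1+/- libraries than in the other 18. Adult heart RNA mixed into the samples would bring the abundant heart transcripts together, and 6 of the 18 tested were called higher, with 2 called lower, 10 not called and a median of 0.23. Tnni3 (-0.36), Mb (0.25) and Mybpc3 (-0.09) were not called, which argues against it, although brain also expresses 11 of the 18 above 1 CPM. A library batch shared by these animals would give the separation seen for Ankrd1 in 10 of 10 libraries, and so would the genotype or its breeding, so these cannot be told apart because the PS19 Cx3cr1+/- animals form every library of that genotype. Not tested and open are reads shared between paralogs and RNA or reads of other tissues or animals, since in some of these libraries airway Scgb1a1 reached 11.2 CPM (at most 0.102 in the other 18) and olfactory Omp 41 CPM (at most 3.3), and Uty in females averaged 5.42% of the male mean against 2.25%.

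More genes were called in females than in males for PS19 Cx3cr1+/- against PS19, with a ratio of 28.7, and leaving out PS19 male replicates 4 and 5 gave 149 male calls, which does not close the gap. In a fit that split NTg and PS19 mice on the length trend and left PS19 Cx3cr1+/- mice whole, the same PS19 Cx3cr1+/- males against the same 3 PS19 males gave 1689 calls, with 5043 in females, so the part of these 2 libraries stays open. Without the 7 libraries at the ends of the length trend the ratio was 1.65, without 6 of them it was 4.04, and with the length and GC offset it was 9.74. Leaving out the 7 also set the PS19 males kept (slopes -0.082, -0.231 and -0.095) below the PS19 Cx3cr1+/- males kept (-0.031 to 0.095). Spread of male libraries along the trend is thus a candidate for part of the gap. The fall of the ratio cannot tell it from a trend difference made between the male groups. A sex-dependent effect of Cx3cr1 loss cannot be told apart from the trend, because the tests of the difference go both ways. After the offset, 11.3% of genes had an unadjusted interaction p under 0.05, against 5.12% without the 6 libraries, 6.85% without the 7 and 4.2% without PS19 male replicates 4 and 5. edgeR quasi-likelihood called 0 genes in each of these, with 2276 at that level in all libraries, where DESeq2 called 6 and limma voom 1.

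The genes called in PS19 Cx3cr1+/- against PS19 females may in part follow a length trend between libraries. Across genes, which are not independent replicates, their changes correlated at 0.46 with the difference of NTg male replicates 3 to 5 from 1 and 2, which share genotype and sex and no library with the females. A smooth trend on length and GC content as the whole cause is argued against, narrowly, by 1286 of 2552 calls kept in direction with the offset. A lower microglial share as large as the Cx3cr1 change (-0.47) is argued against by a median of 0.04 for homeostatic microglial genes (95% interval -0.11 to 0.42). That interval is over genes, which are not independent replicates, and the members ran from -0.86 to 1.22, with 10 of 18 higher. Cx3cr1 is also lowered by the genotype itself and was not called in females, so a smaller loss of microglia stays open. The effect of genotype remains open for the rest, and it cannot be told apart from a library batch shared by the PS19 Cx3cr1+/- animals.

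Other splits of the same libraries were run for each comparison. Chance can be excluded for PS19 Cx3cr1+/- against PS19 in females (2552 genes, the highest other split 17, 1 of 56 splits as large) and over both sexes (2419, highest other 1846, 1 of 100). It can also be excluded for PS19 Cx3cr1+/- against NTg in females (76, highest other 49, 1 of 100) and in males (68, highest other 38, 1 of 100). These splits show only that the groups differ. They do not keep the length-trend subsets apart, and all 5 PS19 Cx3cr1+/- females lay above all 3 PS19 females on that trend. Nor can they tell the genotype from a library batch shared by the PS19 Cx3cr1+/- animals. For PS19 against NTg in males, 2 of 100 splits were as large (3 genes, highest other 84). Over both sexes, 4 of 100 were (8 genes, highest other 4725). Both shares are under 0.05, but other splits called more genes than the real one, so chance is not excluded. Here too the splits do not keep the length-trend subsets apart. Within these subsets edgeR quasi-likelihood called 0 and 0 genes in males, with 318 and 304 at an unadjusted p under 0.05. In all males 555 genes were at that level, where 863 would be expected (DESeq2 called 6 genes and limma voom 2), and Ccl3 and Slamf8 were lost in 9 and 8 of 10 refits. Their changes were nonetheless of like size in the 2 subsets (3.44 and 2.54 for Ccl3, 1.90 and 2.32 for Slamf8) and had the same direction in females, which are other animals (2.17 and 1.39 among those with the lower trend). Both genes passed in each of the 18 refits over both sexes, and both calls ended there without 6 or 7 libraries at the ends of the length trend. The subsets and the refits reuse the males in which the genes were picked, so neither is a test of chance. Prnp kept its call in each refit without 1 library, though not in males without 6 libraries or in females with the replicate block. The splits alone do not exclude chance for PS19 against NTg in females (1, highest other 5, 4 of 56) or for PS19 Cx3cr1+/- against PS19 in males (89, highest other 4162, 7 of 100). Other values argue against chance for the female Prnp call and bear on the male calls. Prnp, the female gene, ran from 1490 to 1631 CPM in PS19 and from 595.1 to 739.5 CPM in NTg and was also called in males. Of the 89 male calls, 64 were shared in direction with the females, which are other animals, where 5.76 would be expected if genes were independent. Genes are not independent, and the female calls also shared 850 genes, where 181 would be expected, with a split inside NTg males. The excess alone thus does not exclude chance, and a batch shared by the PS19 Cx3cr1+/- animals would also give shared calls. For the sex differences a real count of 0 is reached by 100 of 100 splits whatever the data, so these splits say nothing about chance (edgeR quasi-likelihood, 613 and 2276 at an unadjusted p under 0.05, highest others 2211 and 3459; DESeq2 called 0 and 6, limma voom 0 and 1). Splits that call several times the real count point to a structure of the samples. The male split with 4162 genes put PS19 replicates 4 and 5 with PS19 Cx3cr1+/- replicates 1, 3 and 4 and so followed the length trend, and the values apart were 1689 and 45 calls against the PS19 males below and above a trend of 0.1.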

How the results depend on the processing

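The length and GC offset, the fits without 6 or 7 libraries at the ends of the length trend and the fit without PS19 male replicates 4 and 5 are tests chosen after the result was seen. Counts follow the order PS19 against NTg, PS19 Cx3cr1+/- against PS19 and PS19 Cx3cr1+/- against NTg, females before males, and those within 1.5 times the reported count are left out. The cause was not tested for any of the changed counts.

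In a fit of the compared groups alone the counts were 10, 1, 6485, 20, 448 and 20, and 33 for PS19 against NTg over both sexes. With DESeq2, PS19 against NTg gave 59 and 6, PS19 Cx3cr1+/- against PS19 males 212, PS19 Cx3cr1+/- against NTg 197 and 182, PS19 against NTg over both sexes 59 and the sex difference of Cx3cr1 loss 6. With limma voom, PS19 against NTg females gave 1032, PS19 Cx3cr1+/- against PS19 gave 8558 and 48, PS19 Cx3cr1+/- against NTg 3341 and 172, the averages 3155 and 6910 and the sex difference of Cx3cr1 loss 1. With a filter at a mean of 1 CPM, PS19 against NTg males gave 1 and PS19 Cx3cr1+/- against NTg males 39.

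With the replicate number as a block, PS19 against NTg gave 0 in females (edgeR quasi-likelihood, 1453 at an unadjusted p under 0.05; DESeq2 59 and limma voom 1032 without the block) and 1 in males, PS19 Cx3cr1+/- against PS19 gave 1385 and 56, PS19 Cx3cr1+/- against NTg males 43 and PS19 against NTg over both sexes 3. Whether the numbers pair animals is not given in the labels. Residuals of like-numbered NTg and PS19 males correlated from -0.16 to 0.42 across genes, with 4 of 5 pairs above 0.1. Their mean was 0.27, against -0.07 for unlike numbers. NTg and PS19 males of replicates 1, 2, 4 and 5 lay on the same side of a length trend of 0.1, and those of replicate 3 did not. A pairing by number thus cannot be told apart from the length trend here. In the other group pairs, 0 to 2 like-numbered pairs were above 0.1.

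With the length and GC offset, PS19 against NTg gave 2 and 1, PS19 Cx3cr1+/- against PS19 males 204 and PS19 Cx3cr1+/- against NTg females 119. Without 6 libraries, PS19 against NTg males gave 0 (edgeR quasi-likelihood), PS19 Cx3cr1+/- against PS19 gave 4427 and 1097, PS19 Cx3cr1+/- against NTg 1232 and 13 and the averages 1 and 6210. Without 7, the counts were 8, 1, 6115, 3707, 2941 and 270, and 1 and 7913 for the averages. Without PS19 male replicates 4 and 5, PS19 against NTg males gave 1, PS19 Cx3cr1+/- against PS19 males 149 and the averages 2070 and 5882. Prnp in PS19 Cx3cr1+/- against PS19 males changed sign without 7 libraries (-0.42, adjusted p = 0.0031, edgeR quasi-likelihood), and proteasome genes in PS19 Cx3cr1+/- against NTg males turned from higher to lower without 6 (camera adjusted p = 0.0119) or 7 (1.71e-05).

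Leaving out each library in turn gave 1 to 14 and 1 to 4 genes for PS19 against NTg, 111 to 3230 and 35 to 161 for PS19 Cx3cr1+/- against PS19, 22 to 120 and 21 to 114 for PS19 Cx3cr1+/- against NTg, 4 to 11 and 1061 to 4198 for the averages, and 0 to 0 and 0 to 2 for the sex differences. Of 541 values of named genes, 536 kept direction and call with RLE size factors, 504 with DESeq2, 435 with limma voom, 518 with no filter, 480 with the block and 476 with the offset, and 514 of 523 with the stricter filter.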

Other observations

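Transcripts of the other sex were low in every library and higher on average in PS19 Cx3cr1+/- animals, with overlapping ranges, seen after the fact. Ddx3y in females averaged 2.87% of the male mean in NTg and PS19 (n = 8) and 4.44% in PS19 Cx3cr1+/- (n = 5), Eif2s3y 3.18% and 5.53%, Kdm5d 2.94% and 4.46% and Uty 2.25% and 5.42%. Xist in males averaged 2.2% of the female mean (1.02% to 3.64%, n = 10) and 3.22% (2.63% to 3.73%, n = 5). Its mean was 9.096 CPM in NTg, 15.12 CPM in PS19 and 17.74 CPM in PS19 Cx3cr1+/- males. Ddx3y in females ran from 1.53% to 5% in NTg and PS19 and from 3.28% to 5.11% in PS19 Cx3cr1+/-. In PS19 Cx3cr1+/- against PS19 females, Eif2s3y (1.27, adjusted p = 0.0101), Uty (1.30, adjusted p = 0.0201) and Kdm5d (0.88, adjusted p = 0.0239) rose by edgeR quasi-likelihood, and Ddx3y did not pass (0.80, adjusted p = 0.0501). The Eif2s3y call was lost without PS19 female replicate 1, and those of Uty and Kdm5d in 3 and 5 of 8 refits. Kdm5d was also lost with the length and GC offset. In males against NTg, Xist rose by 0.96 (adjusted p = 0.0454, edgeR quasi-likelihood), a call lost in 9 of 10 refits without 1 library. No cause was tested.

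Olfactory, airway, cerebellar and choroid plexus genes varied widely among PS19 Cx3cr1+/- libraries. The olfactory gene Omp ran from 1.06 to 41 CPM there and from 0.49 to 3.3 CPM in the other 18, and the airway gene Scgb1a1 from 0 to 11.2 CPM and from 0 to 0.102 CPM. Cerebellar Gabra6 ran from 4.76 to 183 CPM and Pcp2 from 0.472 to 35.3 CPM, against 54 to 182 CPM and 13.1 to 33.3 CPM. Ttr of the choroid plexus ran from 67.4 to 1465 CPM against 508 to 1611 CPM.

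Lists that the results leave out ranged from 0 to 5 calls over the 10 comparisons, with striatal genes called in 5 and NF-kB and cytokine genes in 4. Mural cell genes (smallest camera adjusted p = 0.0678, PS19 against NTg over both sexes, median -0.15) and lymphocyte genes (0.182, PS19 against NTg females, median 0.57) were called in 0 of 10. Astrocyte and ependymal genes were called for the sex difference of PS19 against NTg alone. Hypothalamus and pituitary genes (median 0.17, camera adjusted p = 0.0384) and stress response genes (median -0.13, camera adjusted p = 0.0253) were called in PS19 Cx3cr1+/- against NTg females alone, each at adjusted p = 0.566 with an estimated correlation. Inhibitory neuron genes were called in PS19 Cx3cr1+/- against PS19 males alone (median 0.12, camera adjusted p = 0.0433, adjusted p = 0.458 with an estimated correlation). Striatal genes were lower in PS19 against NTg in females (median -0.32, camera adjusted p = 0.0108, adjusted p = 0.763 with an estimated correlation) and in males (median -0.28, camera adjusted p = 1.29e-05, adjusted p = 0.364 with an estimated correlation). The smallest p came in PS19 Cx3cr1+/- against NTg males for striatal (median -0.38, camera adjusted p = 1.01e-06), erythroid (1.28, 4.02e-05), meningeal (0.17, 0.000677), border macrophage (0.31, 0.000677) and heat shock genes (-0.12, 0.00819), with adjusted p = 0.232, 0.127, 0.309, 0.136 and 0.314 with an estimated correlation. For NF-kB and cytokine genes it came in PS19 against NTg males (median 0.17, camera adjusted p = 5.27e-05, adjusted p = 0.176 with an estimated correlation). The hypothalamus call was lost without NTg female replicate 2 or 4 or PS19 Cx3cr1+/- female replicate 2 or 5, the stress response call without NTg female replicate 1 or PS19 Cx3cr1+/- female replicate 1 or 5, and the heat shock call without replicate 4 of either male group. The inhibitory neuron call was lost without PS19 male replicate 3, 4 or 5 or PS19 Cx3cr1+/- male replicate 4 or 5.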
